A study of Homo sapiens with 4 samples.

How the data were processed

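RNA from Jurkat cells was sequenced in 2 libraries with an shRNA against GFP (control) and 2 with an shRNA against ARIEL. Per the labels' protocols, infected cells were selected with 0.7 µg/ml puromycin for at least 36 h, cells were counted, ERCC spike-in RNA was added by cell number, and strand-specific libraries were read as 100-base pairs. Groups and replicate numbers come from the sample titles.

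The deposited table covers 22361 genes or loci: 20125 with an Ensembl gene ID and 2236 XLOC loci. The submitters' processing notes name STAR 2.5.2a, HTSeq 0.6.1, DESeq2 1.12.4 and build hg19, without stating their roles; the annotation and filters are not given in the sources used here. Per the file headers, the authors deposited 1 rlog value per gene and library, on the log2 scale, and beside it the log2 fold change with its standard error, a test score (the fold change over its standard error, checked to within 5.98e-07), a p-value and an adjusted p. What the size factors were computed from is not stated. The table gives no counts, so library depth is unknown and no counting error can be given. It holds 0 spike-in rows, so spike-in scaling was not analysed here. A set of 4365 rows is listed at 0 in every library. Of 29 names that a spreadsheet had turned into dates, 28 were restored from the gene ID. Coordinates are not given, since the reference used here is a different build; GENCODE 29, matched by gene ID for 19320 of the Ensembl rows, was used for gene class, transcript length, GC content, 3′ UTR sequence and overlapping genes.

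The design fixed before the data were examined called for a count test, or for limma on log2(value + 1) if the file held normalized values. Since the values are already logarithms, limma 3.58.1 (lmFit and eBayes with a trend on level, R 4.3.3) was run on the rlog values directly with no pseudocount. The genes tested were the 14601 with a mean rlog of at least log2 of 10, and p-values were adjusted by Benjamini-Hochberg at 0.05. The estimated prior degrees of freedom were infinite, so all genes of a level share 1 spread; this makes the test strong with 2 replicates per group, and wrong for genes that vary more than others of their level. Median SE was 0.04. The rlog transform shrinks differences, most for low genes: the slope of the rlog difference on the deposited fold change was 0.182 below a mean rlog of 5 and 0.557 from 13 up. On simulated values for this comparison over 14601 genes, 20.9% of planted changes of 0.1, 100% of 0.25 and 100% of 0.5 were recovered, with 0.0417% of unchanged genes called. The simulated noise was independent between genes, with 1 spread per level as the test assumes. These rates therefore do not cover genes that vary more than others of their level. Changes were planted in 67, 67 and 66 genes, against 44.4% of genes called in the data, so recovery in the data may differ. With a trend on GC content planted in the knockdown libraries 13.5% of unchanged genes were called, and 0.0479% once it was removed, so the calls on values that carry such a trend include genes moved by it.

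The 27 gene lists were fixed before the data were examined; the 23 with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over the lists. With a correlation estimated from the data, camera passed 0 of the 9 called lists, and 0 lists had an unadjusted p under 0.05. Both that estimate and the p-value of that test rest on 2 residual degrees of freedom, so a list could hardly pass. The T-cell receptor activation and immediate early list, with an estimated correlation of only 0.0257, also lost its call. Such a loss therefore does not show that correlation between genes made a call, and the calls rest on the preset value. Named genes were the 7 fixed in advance (ARIEL, ARID5B, MYC, TAL1, GATA3, RUNX1, MYB), the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, with a mean of at least 50 on the linear scale and a gene symbol, and up to 4 called members per list with the smallest adjusted p; the 5 risen ATF4 list members were added after their values were seen. LMO1, TCF3, LDB1, TCF12 and CBFB of the TAL1 complex list were also added then, outside the counts of calls lost.

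A trend check and a sequence check were added after the data were seen. The trend of each library with transcript GC content and length was removed by spline regression (5 degrees of freedom each) over the 12719 genes with both properties. All 15889 words of 7 bases found in the 3′ UTRs of at least 100 of 12487 genes were tested by regression of the rlog difference on carrying the word, with UTR and transcript length, GC and level as covariates, against 100 shuffles; the choice was repeated on a random 6243 genes and without the 8 largest falls (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The 2 strongest words with lower carriers, GATGACA and AGATGAC, are called fall words, and TGTTGTC and GTTGTCA rise words. Alternatives tried were filters, scalings, pseudocounts, a replicate block, leaving out each library, thresholds, other set tests, robust and unpooled spread, the trend removal, and leaving out carriers of the 4 words.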

Results

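RNA was measured in 4 libraries of Jurkat cells, a human line grown from a T-cell acute lymphoblastic leukaemia (T-ALL) whose growth depends on the transcription factor TAL1. In 2 libraries the cells carried an shRNA against ARIEL, a long non-coding RNA, and in 2 they carried a control shRNA against GFP. Cells were collected 72 h after lentiviral infection. The comparison asks which RNAs change when ARIEL is depleted. The values are regularised log (rlog) expression on the log2 scale, a transform that pulls noisy low values towards the gene's mean, so differences on it understate the change. Read totals are not part of the table, and the depth of each library is unknown. Median rlog over the 14601 tested genes was 11.32 in each control library and between 11.31 and 11.32 in the knockdown libraries. Nothing says that replicates were separate cultures, so the p-values measure only the spread between these samples.

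The targeted RNA was lower in both knockdown libraries. The table has no row named ARIEL; from background knowledge of the study, ARIEL is the unannotated locus XLOC_005968 on chromosome 10, a link that the table itself does not state. XLOC_005968 had rlog values of 12.02 and 11.91 in the control libraries and 10.58 and 10.55 in the knockdown libraries, a difference of -1.40 ± 0.04 (SE, n = 2 per group; limma, adjusted p = 1.22e-249). In the authors' deposited table it was 6.50-fold lower (log2 fold change -2.70 ± 0.09, SE).

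Several transcription factors of the TAL1-centred regulatory circuit of T-ALL cells fell with it. ARID5B, also on chromosome 10 and an activator in that circuit, went from 14.01 ± 0.03 (SD, n = 2) in control libraries to 13.56 ± 0.02 in knockdown libraries, a difference of -0.46 ± 0.03 (SE). GATA3 differed by -0.27 ± 0.05, MYB by -0.23 ± 0.03, TAL1 itself by -0.23 ± 0.03 and RUNX1 by -0.15 ± 0.03. MYC, a regulator of growth, rose by 0.14 ± 0.03 (limma, adjusted p = 8.88e-05), the largest adjusted p among these genes. In the authors' deposited table ARID5B was 1.77-fold lower, GATA3 1.48-fold, MYB 1.34-fold and TAL1 1.33-fold lower, RUNX1 had a log2 fold change of -0.27, and MYC was 1.18-fold higher. The 3′ UTRs of TAL1 and RUNX1 each carry both of the 7-base words GATGACA and AGATGAC, whose carriers were lower over all genes, while those of ARID5B, GATA3, MYB and MYC carry neither. RUNX1 also carries both of the words TGTTGTC and GTTGTCA, whose carriers were higher after adjustment for UTR properties, and TAL1 and ARID5B each carry 1 of them. With each gene's own variance on 2 residual degrees of freedom, with no sharing of the spread between genes, none of these 7 calls passed (adjusted p 0.0791 to 0.195).

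**Figure D1:**
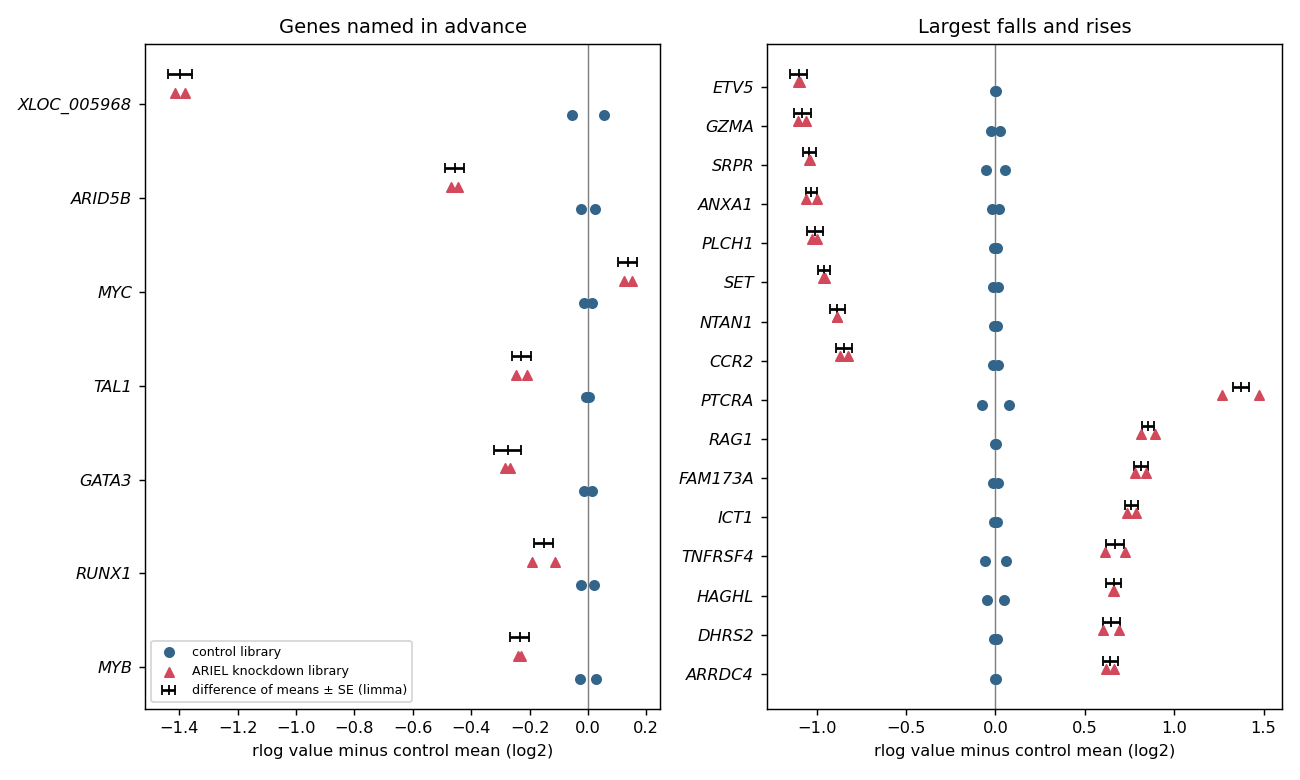
Each point is the rlog value of 1 library minus the mean of the control libraries of that gene, for the genes named in advance (left) and the 8 largest falls and 8 largest rises (right); bars give the difference of group means with its standard error from limma. XLOC_005968 lies at -1.40, ARID5B at -0.46 and PTCRA at 1.37.

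Genes known to be activated by TAL1 in T-ALL were lower as a group. Of 16 tested, 12 fell, 1 rose and 3 were not called, with the same counts adjusted over the list alone, and the median difference was -0.31 (camera, adjusted p = 4.76e-07; adjusted p = 0.584 with an estimated correlation). The GIMAP genes, which encode small GTPases of lymphocytes and lie together on chromosome 7, were among the falls: GIMAP7 differed by -0.66 ± 0.04 (SE), GIMAP4 by -0.61 ± 0.04 and GIMAP1 by -0.58 ± 0.04. ALDH1A2, a retinoic acid synthesis enzyme, differed by -0.50 ± 0.03. ARID5B and MYB belong to this list and to that of the TAL1 complex. In the TAL1 complex and its core circuit, 7 of 13 tested members fell, among them ETV6 at -0.24 ± 0.03, and 4 rose (8 and 5 adjusted over the list alone). The 4 that rose were LMO1 (0.22 ± 0.05), MYC, TCF3 (0.12 ± 0.03) and LDB1 (0.12 ± 0.03), while TCF12 and CBFB were not called. The list was not called (camera, adjusted p = 0.127, with 0.584 for an estimated correlation and 0.777 without carriers of the 3′ UTR words), though it passed on the authors' deposited statistic (0.0199). Leaving out carriers drops genes with any of the 4 words, rise words included. It thus removes ARID5B, which carries no fall word, as well as TAL1, RUNX1 and ETV6. Leaving out carriers of the fall words alone was not tested.

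Genes around ARID5B on 10q21 moved in both directions. Of 12 tested, 4 rose and 4 fell (5 and 4 adjusted over the list alone), with CCDC6 at 0.47 ± 0.04 (SE) and JMJD1C at -0.24 ± 0.03 beside ARID5B (camera, adjusted p = 0.794). Mediator complex subunits, which join enhancers and promoters, had 6 of 32 members higher and 9 lower, by the list alone as well. MED28 had the largest fall of these, a difference of -0.42 ± 0.03, and its 3′ UTR carries both fall words and 1 rise word. CDK8, a Mediator kinase, rose by 0.48 ± 0.04 and its paralogue CDK19 differed by -0.25 ± 0.04 (camera, adjusted p = 0.794 for the list). CDK19 carries both fall words in its 3′ UTR and CDK8 carries both TGTTGTC and GTTGTCA.

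The 8 largest falls among well-expressed named genes were in genes of varied function. They were ETV5, an ETS-family transcription factor (-1.10 ± 0.05, SE), the granzyme gene GZMA (-1.08 ± 0.05), SRPR, which encodes the signal recognition particle receptor (-1.04 ± 0.04), annexin ANXA1 (-1.03 ± 0.03), the phospholipase gene PLCH1 (-1.01 ± 0.04), the histone chaperone gene SET (-0.96 ± 0.03), NTAN1, an N-terminal amidase (-0.88 ± 0.04), and the chemokine receptor gene CCR2 (-0.85 ± 0.05). SET, an abundant transcript, went from 16.26 ± 0.02 (SD, n = 2) to 15.30 ± 0.01. The authors' deposited table puts these falls between 3.24-fold (NTAN1) and 6.60-fold (CCR2). The 3′ UTRs of ETV5, SRPR and SET carry the word GATGACA and those of the other 5 do not. ETV5 overlaps DGKG on the same strand in GENCODE 29, so their reads cannot be fully separated. The same holds for GIMAP1 with GIMAP5, for SATB1 with TBC1D5 and for DDIT3 with AC022506.1.

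The largest rises included genes of early thymocyte development. PTCRA, the invariant pre-T-cell receptor alpha chain, went from 9.80 ± 0.11 (SD, n = 2) to 11.18 ± 0.14, a difference of 1.37 ± 0.04 (SE), and RAG1, the recombinase subunit that rearranges antigen receptor genes, rose by 0.85 ± 0.03. PTCRA varied more between replicates than the spread shared by level allows for, so its SE of 0.04 is too small. The authors' deposited table has PTCRA 4.02-fold (log2 fold change 2.01 ± 0.20, SE) and RAG1 2.93-fold higher. The others were FAM173A (0.81 ± 0.04), ICT1, a mitochondrial ribosomal peptidyl-tRNA hydrolase (0.76 ± 0.04), the OX40 receptor gene TNFRSF4 (0.67 ± 0.05), HAGHL (0.66 ± 0.04), DHRS2 (0.65 ± 0.05) and ARRDC4 (0.64 ± 0.04). The 3′ UTRs of ICT1 and HAGHL carry both rise words, TGTTGTC and GTTGTCA, and those of RAG1 and ARRDC4 carry 1 of them. PTCRA, FAM173A, TNFRSF4 and DHRS2 carry neither.

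Over all genes, 3224 rose and 3264 fell of 14601 tested (44.4%; limma, adjusted p under 0.05), most by small amounts: the median size of a called difference was 0.15, and 14 rose and 51 fell by at least 1.5-fold on the rlog scale. In 6434 of the 6488 called genes the 2 groups did not overlap, and groups did not overlap in 70.7% of all tested genes, against 33.3% by chance. The authors' deposited table has 2920 genes higher and 2808 lower at an adjusted p under 0.05, of which 258 and 576 changed at least 1.5-fold; 5663 of its 5728 genes were also called here, all in the same direction. The count rests on pooling the spread over genes of similar level: limma without that pooling called 0 genes, with 4561 at an unadjusted p under 0.05 (31.2% of genes). Without ARIEL knockdown replicate 2, 4225 genes were called.

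Genes whose 3′ UTR carries GATGACA or AGATGAC were lower than other genes. Of the 481 genes with a searched 3′ UTR that were at least 1.5-fold lower in the authors' deposited table, 42.2% carried at least 1 of these words, against 15.7% of all 12487 genes searched. The words were chosen on these genes, but the same 2 words were chosen on each of 2 random parts of them. In the genes that took no part in the choice, 45.0% of 231 and 39.6% of 250 fallen genes were carriers. The shares of all genes there were 16.2% and 15.2%, so the excess held outside the choice. The median 3′ UTR of the fallen genes was 1952 bases against 1248. Given UTR and transcript length, GC content and level, GATGACA carriers differed by -0.07 (regression t -17.0), where 100 shuffles of the gene values reached -4.98, and the word's t was -1.66 between control libraries and 1.47 between knockdown libraries. TGTTGTC carriers were 0.05 higher after the same adjustment (t 12.7, with 4.82 the highest of the shuffles). Without adjustment the medians of its carriers and of the other genes were both 0.00. Of the 233 genes at least 1.5-fold higher in the authors' deposited table, 28.8% carried TGTTGTC or GTTGTCA, against 17.6% of all genes searched. The rise words were chosen on these genes, so that share in part restates the choice. It was not measured in genes that took no part. Chosen on 6243 genes drawn at random, the strongest words were the same, and in the other 6244 genes GATGACA had a t of -10.9 and TGTTGTC a t of 6.08. With the 2 parts exchanged GATGACA was again the strongest fall word (t -13.2 in the genes that took no part). The strongest rise word was then GTTGTCT (t 4.35), so the choice of rise words depends on the genes used. Some named genes went against their words: BNIP3, which rose, carries both fall words and the risen PTCRA, FOSB and NOTCH3 carry 1 each (NOTCH3 with 1 rise word). ETV6, which fell, carries both rise words and 1 fall word. Among named genes that went with their words, the risen CCDC6, NPM1 and SLC2A1 carry 1 rise word each and the fallen INSIG1 carries 1 fall word.

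T-lineage genes split. Of 35 tested T cell receptor and T-lineage genes, 18 fell and 9 rose, by the list alone as well (median -0.09; camera, adjusted p = 0.0768; 0.584 with an estimated correlation), with PTCRA and RAG1 at the top and TRAT1, a T-cell receptor adaptor (-0.73 ± 0.04, SE), and the chromatin organiser SATB1 (-0.35 ± 0.03) at the bottom. TRAT1 and SATB1 carry both fall words, and 10 of the 35 members, PTCRA among them, carry at least 1. The list passed the test with the GC and length trend removed (camera, adjusted p = 0.0104), with no filter (0.0302) and on the authors' deposited statistic (0.0224). Among 19 NOTCH1 target genes 9 rose and 4 fell, by the list alone as well, with NOTCH3 at 0.45 ± 0.03, HES4 at 0.43 ± 0.03 and HES1 at -0.60 ± 0.05 (camera, adjusted p = 0.200 for the list). HES1 carries both fall words and 8 of the 19 members at least 1. HES4 varied widely between replicates (SD 0.17 in control and 0.09 in knockdown libraries), so its SE from the spread shared by level is too small. In the authors' deposited table its log2 fold change was 0.58 ± 0.19 (SE).

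The list of T-cell receptor activation and immediate early genes was called higher, though not in every setting. In that list 14 of 25 members rose and 5 fell (15 and 6 adjusted over the list alone), with a median of 0.14 (camera, adjusted p = 0.00361; adjusted p = 0.584 with an estimated correlation). The transcription factor genes JUN (0.60 ± 0.04, SE) and FOSB (0.59 ± 0.05) and the phosphatase gene DUSP2 (0.56 ± 0.03) were higher, while CD69, a surface marker of activation, differed by -0.67 ± 0.04. With the GC and length trend removed the list's median was 0.09 and the call was lost (camera, adjusted p = 0.0890), as it was with no filter (0.108). NF-kappaB target genes were even, with 6 of 21 higher and 6 lower, by the list alone as well, including BIRC3, an apoptosis inhibitor, at -0.29 ± 0.03 (camera, adjusted p = 0.743).

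Genes for making ribosomes and mitochondria rose together by small amounts. Of 74 cytosolic ribosomal protein genes 49 rose and 2 fell (54 and 2 adjusted over the list alone; median 0.10; camera, adjusted p = 1.35e-06; 0.584 with an estimated correlation). The 2 that fell were the stalk protein genes RPLP1 (-0.73 ± 0.03, SE) and RPLP2 (-0.33 ± 0.03), against RPS28 at 0.23 ± 0.03. Of 48 nuclear-encoded respiratory chain genes 28 rose and 1 fell (30 and 2 by the list alone; median 0.10; camera, adjusted p = 3.32e-05; 0.584 with an estimated correlation), with ATP5G1, an ATP synthase subunit, at 0.62 ± 0.03 and NDUFB10 of complex I at 0.27 ± 0.03. Of 38 MYC-regulated nucleolar and metabolic genes 24 rose and 4 fell (26 and 5 by the list alone; median 0.12; camera, adjusted p = 0.000288; 0.584 with an estimated correlation), with nucleophosmin NPM1 at 0.32 ± 0.04 and the ribosome assembly factor RRP9 at 0.29 ± 0.03.

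Replication-dependent histone genes were higher, 34 of 50 rising and 16 not called (35 by the list alone; median 0.11; camera, adjusted p = 4.76e-07; adjusted p = 0.589 with an estimated correlation), with HIST1H2BG at 0.61 ± 0.04 (SE) and HIST1H2AE at 0.55 ± 0.03. The histone list was fixed in advance as a control of RNA quality. Its rise therefore cannot be told apart from a difference in RNA quality between the libraries. The estimated correlation of its members was 0.761, against the preset 0.01 that the call assumes. Histone copies are nearly alike, as are ribosomal protein genes and their pseudogenes, so reads may be split between copies. Glycolysis and hypoxia genes had 16 of 34 members higher and 5 lower, by the list alone as well (median 0.07; camera, adjusted p = 0.00770; adjusted p = 0.589 with an estimated correlation), with the glucose transporter gene SLC2A1 at 0.32 ± 0.03 and BNIP3 at 0.29 ± 0.03. That call was lost without ARIEL knockdown replicate 2 (0.0594) and without carriers of the 3′ UTR words (0.176).

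These shifts stood beside a trend with GC content. Across 12719 genes with transcript properties, the difference between groups rose with transcript GC content (Spearman's rho 0.41, against 0.59 between the control libraries and 0.41 between the knockdown libraries; across genes, which are not independent replicates), from a median of -0.08 in the lowest decile to 0.08 in the highest. A trend also separated replicates, taken as replicate 2 minus replicate 1, from -0.06 to 0.04 between the control libraries and from -0.05 to 0.02 between the knockdown libraries. Its sign follows the replicate numbers, whose meaning is not stated. With the trend with GC and length removed, medians were 0.07 for ribosomal proteins, 0.10 for the respiratory chain and 0.08 for MYC-regulated genes, and these lists were called (camera, adjusted p = 0.000265, 0.000338 and 0.00166). For histones the median of the 23 members with the properties went from 0.09 to 0.05 and the list was not called (adjusted p = 0.195); with 46.0% of members this decides nothing.

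**Figure D2:**
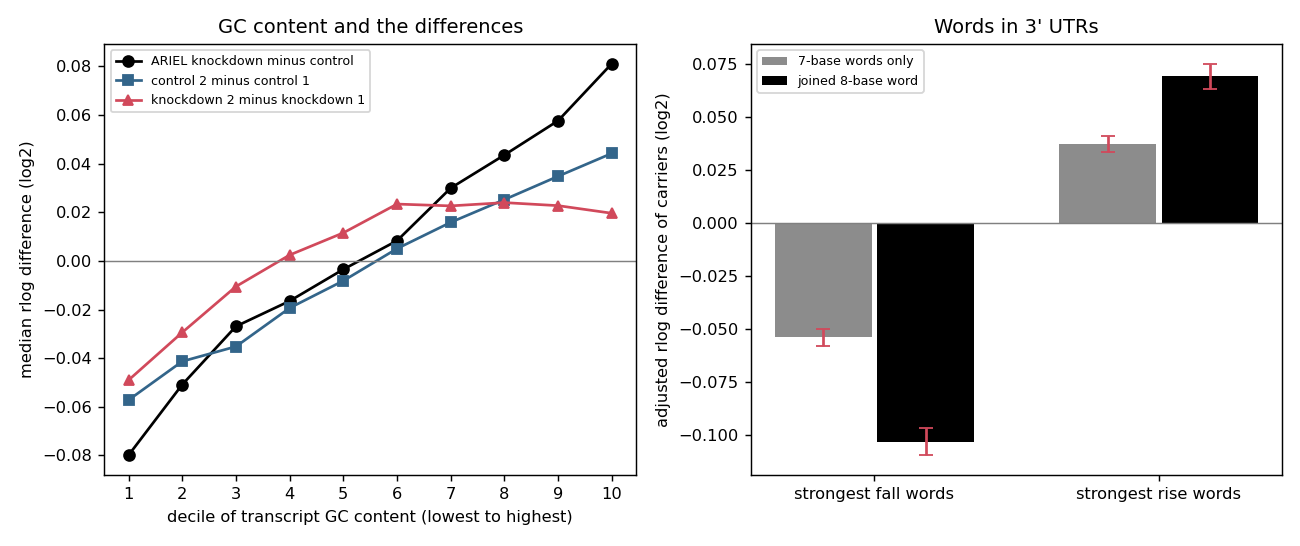
Left: median rlog difference (log2) of genes in each decile of transcript GC content, between groups and between replicates; the line between groups runs from -0.08 to 0.08. Right: rlog difference of genes whose 3′ UTR carries the strongest words, against genes with none, adjusted for UTR and transcript length, GC and level; bars start at 0, error bars are 1 SE across genes, and carriers of the joined 8-base word, over all genes searched, lie at -0.10 (fall words) and 0.07 (rise words).

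Most genes of the amino acid and unfolded protein responses fell. Of 34 ATF4 and unfolded protein response genes 22 fell and 5 rose (23 and 5 adjusted over the list alone), with a median of -0.19 (camera, adjusted p = 2.03e-05; adjusted p = 0.584 with an estimated correlation). ATF4, the transcription factor of the amino acid response, went from 15.80 ± 0.02 (SD, n = 2) to 15.27 ± 0.02, a difference of -0.54 ± 0.03 (SE). SLC7A11, the cystine transporter, differed by -0.77 ± 0.05, the degradation factor SEL1L by -0.48 ± 0.03 and the disulfide isomerase PDIA6 by -0.37 ± 0.03. SEL1L carries both fall words and PDIA6 carries 1. The 5 that rose, named after their values were seen, were the stress factor genes DDIT3 (0.42 ± 0.05) and DDIT4 (0.31 ± 0.03), MTHFD2 (0.19 ± 0.03), SDF2L1 (0.16 ± 0.04) and HSPA5 (0.10 ± 0.03). HSPA5 carries 1 fall word, and MTHFD2 1 fall word and both rise words. Of 23 cholesterol synthesis genes 10 fell and 6 rose (11 and 6 by the list alone; median -0.02; camera, adjusted p = 0.122; 0.589 with an estimated correlation), with INSIG1 at -0.58 ± 0.03 and IDI1 at -0.36 ± 0.03. The list passed with the GC and length trend removed (0.0372), without ARIEL knockdown replicate 2 (0.0211) and on the authors' deposited statistic (0.00914). Heat shock genes were not called as a list, with 3 of 16 higher and 4 lower, by the list alone as well, with HSPA1B at 0.47 ± 0.04 (camera, adjusted p = 0.616).

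The DNA replication list was called slightly lower, though the call did not hold in every setting. Of 39 DNA replication and G1/S genes 19 fell and 5 rose (20 and 5 adjusted over the list alone; median -0.07; camera, adjusted p = 0.0238; adjusted p = 0.589 with an estimated correlation), with the G1/S cyclins CCNE1 at -0.46 ± 0.05 (SE) and CCNE2 at -0.33 ± 0.04. The call was lost without ARIEL knockdown replicate 1 (0.143) and without control replicate 1 (0.0550). G2/M and mitosis genes had 6 of 36 higher and 10 lower, by the list alone as well; the median was 0.00 with a positive sign while the mean, -0.01, and the test pointed down (camera, adjusted p = 0.807), with the mitotic activator CDC20 at 0.20 ± 0.03 and ECT2 at -0.26 ± 0.03. Of 22 p53 target genes 7 rose and 4 fell (9 and 4 by the list alone), with BTG2 at 0.32 ± 0.04 and the death receptor gene FAS at -0.22 ± 0.04 (camera, adjusted p = 0.122). The BCL2 family, which sets the threshold for apoptosis, had 5 of 16 higher and 3 lower, by the list alone as well, with the pro-apoptotic BMF at 0.32 ± 0.04 and BIK at 0.28 ± 0.04 (camera, adjusted p = 0.202). Interferon-stimulated genes had 18 of 35 lower and 9 higher, by the list alone as well (median -0.09; camera, adjusted p = 0.107), with RSAD2 at -0.44 ± 0.04, XAF1 at -0.38 ± 0.04 and BST2 at 0.30 ± 0.03. RSAD2 carries 1 fall word and 1 rise word and XAF1 both fall words.

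Markers of other cell types served as controls. NK and cytotoxic markers had 2 of 6 lower and 1 higher, by the list alone as well, with GZMA far below the rest (camera, adjusted p = 0.187; 0.584 with an estimated correlation and 0.0224 on the authors' deposited statistic). B cell markers had 2 of 5 higher and 1 lower (3 and 1 by the list alone), with CD79A at 0.29 ± 0.04 (SE; camera, adjusted p = 0.202). Too few members were tested for a list test in 4 lists. The 3 myeloid markers tested, ITGAM, CD14 and CD68, were not called over all genes or over the list alone. Of 2 erythroid markers KLF1 was lower (-0.07 ± 0.03), and of 2 epithelial and fibroblast markers COL1A1 was lower (-0.18 ± 0.04) and KRT8 higher (0.07 ± 0.03), each with the same count by the list alone. In the authors' deposited table KLF1 (adjusted p = 0.167), KRT8 (0.122) and GZMB, the NK and cytotoxic marker that was higher (0.0941), did not pass. No mitochondrially encoded mRNA was among the rows, so that list, like the histones a control of RNA quality, was not analysed here.

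**Figure D3:**
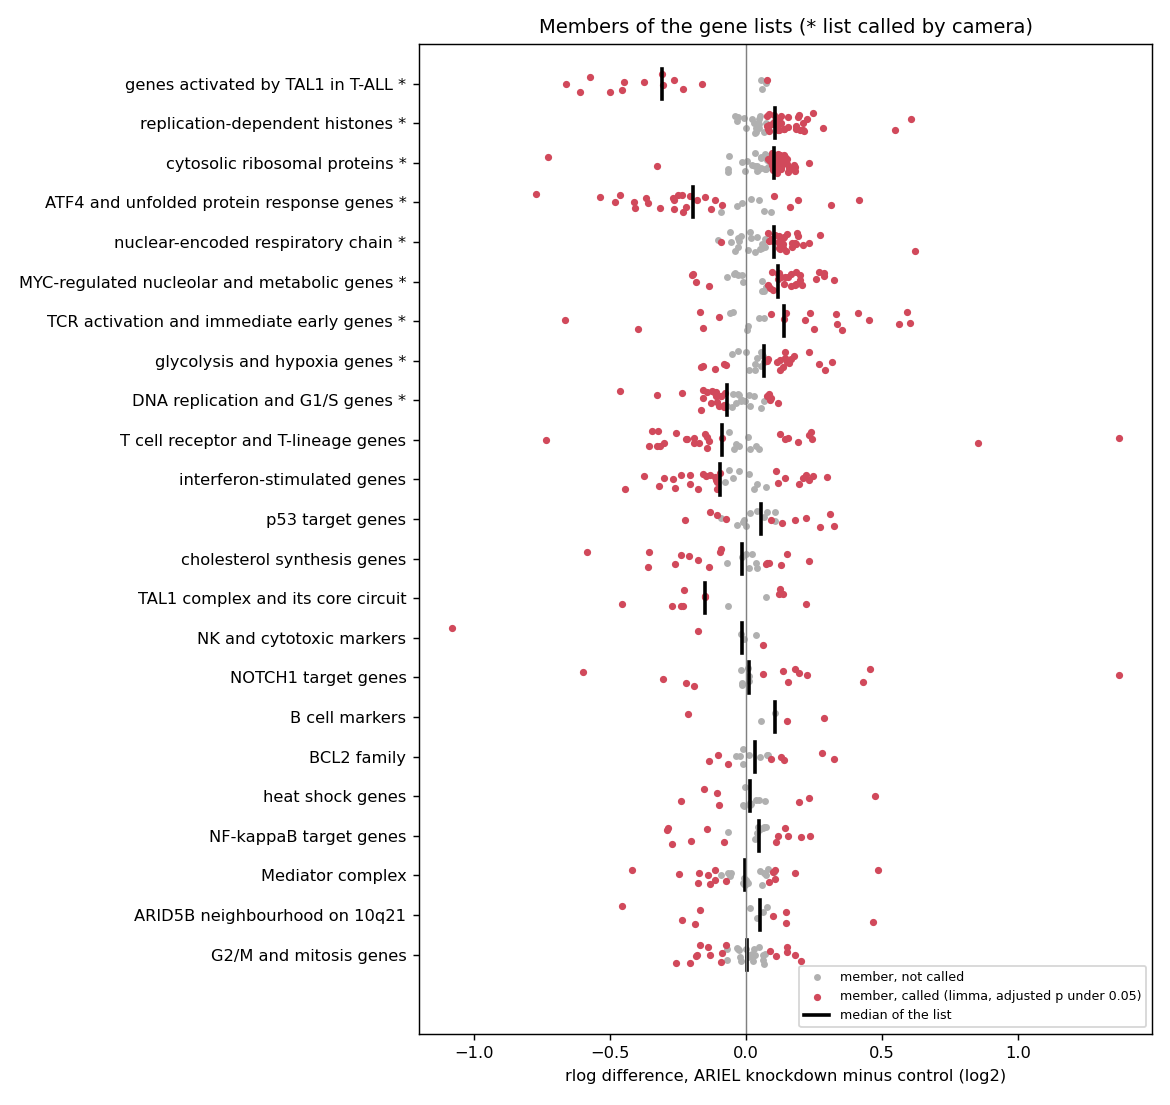
Each point is the rlog difference (log2, ARIEL knockdown minus control) of 1 tested member of a gene list; red members passed the test over all genes, grey ones did not, and the black line is the list's median. The TAL1-activated list has its median at -0.31 and the ATF4 list at -0.19, while the ribosomal protein, respiratory chain and histone medians lie at 0.10, 0.10 and 0.11.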

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

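The median-centred, robust, unpooled, trend-removed and word-carrier settings and the set test on the deposited statistic were chosen after the data were seen. No named gene or list that was called changed direction under any alternative run. Without pooling of the spread limma called 0 genes (0 higher, 0 lower), with 4561 at an unadjusted p under 0.05 and the authors' deposited table at 5728; the differences of XLOC_005968 (-1.40), ARID5B (-0.46), GATA3 (-0.27), MYB (-0.23), TAL1 (-0.23), RUNX1 (-0.15) and MYC (0.14) are then the same and their calls are lost, because 2 degrees of freedom per gene are left. Asking for a 1.5-fold rlog difference left 65 genes (14 higher, 51 lower). Leaving out 1 library in turn, where the lone library is assumed to vary like the others, gave 4225 to 6188 genes (2004 to 3061 higher, 2221 to 3127 lower), lowest without ARIEL knockdown replicate 2, and 8 to 11 lists; XLOC_005968 then differed by -1.45 to -1.34, ARID5B by -0.48 to -0.43, GATA3 by -0.29 to -0.26, MYB by -0.26 to -0.21, TAL1 by -0.25 to -0.21, RUNX1 by -0.19 to -0.11 and MYC by 0.12 to 0.15. Leaving out carriers of the 3′ UTR words removed genes from the test and left 2093 lower (2527 higher, 8 lists). With the GC and length trend removed 6699 of 12719 tested genes were called, of which 4715 were among the 6488. With the trend left in, 6038 of the same 12719 genes were called, of which 5948 were among the 6488. Filters, scalings and pseudocounts gave 5988 to 6508 genes, and 9 lists each. The split moved with the scaling, to 3541 higher and 2930 lower with upper-quartile scaling and 3452 and 3052 with median-centred libraries. In the main fit it was 3224 and 3264. With an estimated correlation camera passed 0 lists, and 0 had an unadjusted p under 0.05. That test has 2 degrees of freedom per gene, so it decides little. The set test fry, which does not compare a list with other genes, called 13. Over all alternatives 19 list tests lost and 20 gained a call, and 134 calls of the 106 other named genes were lost, 106 of them without pooling. What the replicate numbers mark is not stated. Same-numbered deviations correlated at 0.198 across genes over 2 pairs, and replicate 2 minus replicate 1 rose with GC content in both groups. A condition shared by same-numbered libraries is thus possible, which the main fit leaves out, and 2 pairs cannot settle it. The replicate block gave 7426 genes and 9 lists and changed no call of a named gene or list. TMM against size factors, count tests, limma-voom and spike-in scaling were not run, since they need counts or spike-in rows.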

Other observations

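The family scan below, the tests of a scaling offset, of the histone part and of the shared rise word, and those on genes that took no part in choosing the words were chosen after the results were seen. Among 142 families of gene names with at least 10 tested members, 5 were called by camera, all higher: histones (HIST), RPL, RPS and the mitochondrial ribosomal proteins MRPL and MRPS, which no fixed list held. Of 47 MRPL genes 34 rose and 1 fell (median 0.12; camera, adjusted p = 2.82e-06), and of 30 MRPS genes 17 rose and 13 were not called (median 0.10; adjusted p = 0.00190). With the GC and length trend removed their medians were 0.08 and 0.09 and both were called (camera, adjusted p = 0.000619 and 0.00330), as were RPL and RPS. The 35 of 68 histones with the properties went from a median of 0.08 to 0.04 and were not called (0.433). With an estimated correlation camera passed 0 families, and 0 had an unadjusted p under 0.05. That test rests on 2 residual degrees of freedom, so it decides little. Unannotated XLOC loci fell more often than they rose, with 321 lower and 132 higher of 1647 tested.

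The ribosomal protein, respiratory chain, MYC-regulated and histone lists rose together, by 0.11 at the median of their 210 members. A trend with GC and length as the whole source is argued against, since the median of the 181 members with properties was 0.0776 after its removal (bootstrap 95% interval 0.0698 to 0.0944) and 0.101 before. A difference that also separates replicates is argued against by the larger shift within a group, 0.0216 (0.0159 to 0.0256, between the knockdown libraries), against 0.11 between groups. All intervals in this paragraph resample genes as if they were independent, so they give the spread across genes and not that between libraries. The rise cannot be told apart from an offset in scaling (gap of 0.11 to the median of the other genes, 0.10 to 0.12), because centring of the libraries fixes that median near 0. For histones alone it cannot be told apart from the GC and length trend (median 0.0523 after removal, interval 0.0159 to 0.107), because 46.0% of members have the properties. The histone list was also fixed as a control of RNA quality, so its rise may mark a difference between the libraries. For the lists other than histones, a response of growth genes to ARIEL depletion, alongside the rise of MYC, may account for the rest. That is a hypothesis that these libraries cannot separate from other effects of the hairpins.

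Genes of unrelated function were among the largest falls, and of these 8 SET and ANXA1 were abundant. A candidate explanation is a seed match of the knockdown hairpin: chosen without the 8 largest falls, the strongest word was GATGACA (t -16.7), and 3 of those 8 carry it where their UTR and transcript length, GC and level lead to expect 0.484 (exact Poisson-binomial test on chances from a logistic regression over the other genes, one-sided, p = 0.00792). As that explanation predicts, genes whose 3′ UTR joins both fall words into 8 bases were lower than those with a 7-base word alone, by -0.0434 (95% interval -0.0623 to -0.0245) in the 6244 genes that took no part in choosing the words. The mirror case, genes with rise words that are repressed by the control hairpin, had a t of 12.7, but its longer match cannot be told apart from none in those 6244 genes (0.0159, interval -0.00210 to 0.0338), since the interval includes 0; over all genes, which also chose the words, it was 0.0319 (0.0190 to 0.0448); the hairpin sequences are not given in the sources used here, so neither match was checked. Part of the falls of TAL1 and RUNX1 may come from such a match, and so may falls downstream of TAL1 in genes that carry no fall word, such as ARID5B, GATA3 and MYB; these libraries do not separate that from a loss of ARIEL.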
